A study of Mus musculus with 12 samples.

How the data were processed

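The samples were 12 RNA libraries from J1 mouse embryonic stem cells grown on irradiated fibroblast feeders. The cells carried a scramble shRNA, an shRNA against Mettl14 or an shRNA against Mettl3. Per the labels' protocols, fragmented poly(A) RNA was immunoprecipitated with an anti-m6A antibody, which gave 6 IP libraries, 2 in each of 3 groups. The 6 libraries labelled with no antibody have no columns of their own in the deposited tables and were not analysed here. Per the submitters' processing notes, CASAVA 1.8.2, cutadapt 1.1, Bowtie 0.12.7, TopHat2 2.0.6, SAMtools 0.1.18 and Picard 1.74 were used, and the genome build was mm10. The order of these steps, the peak caller's version and the Ensembl release behind the gene names are not given in the sources used here.

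The authors deposited 4 tables, each a list of peaks from 1 knockdown IP library and 1 scramble IP library. Per the file headers, peaks carry MACS names and were called for each IP library against its own control library, strand by strand. The tables fall into 2 sets that share no library. Within a set, the Mettl14 and the Mettl3 table use the same scramble library. The names set 1 and set 2 only separate the tables. No source used here states which replicate number of the labels belongs to a set.

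Per the file headers, each peak carries a tag count in its own library. The deposited fold enrichment is the ratio of IP to its own control within the peak, by the peak caller. The deposited scaled enrichment is that ratio multiplied by 1 constant per table for knockdown peaks. The constants were 0.906 and 0.777 for Mettl14 in set 1 and set 2, and 1.00 and 0.609 for Mettl3, and their basis is not given in the sources used here. Per the file headers, a further column holds the knockdown-over-scramble comparison as a signed fold score, which was present only for peaks found in both libraries. Solving it for the scramble value returned deposited scramble enrichments, which fixed its meaning. The deposited peak score is minus 10 times log10 of the caller's p-value, and the deposited FDR is in percent. The highest FDR listed was 9.99%. Peak scores and folds were the authors' own values throughout.

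The signed fold was turned into a log2 change of knockdown over scramble. A peak was lost if listed in the scramble library alone, new if listed in the knockdown library alone and shared if listed in both, as the authors' columns mark it. A gene was lower in a table if each of its listed peaks was lost or had a negative log2 change, higher if each was new or had a positive one, and of both kinds otherwise. With several shared peaks, the one with the largest change in the called direction gave a named gene's log2 change, and their mean was used for correlations across genes. The peaks behind a gene's set 1 and set 2 values can therefore differ, and each fold compares enrichments over regions called separately in each library, whose widths can differ. The tables hold no value per library over common regions, so no model of condition was fitted. The result for each knockdown was therefore the number of peaks and genes lower and higher in each table, and of genes with the same call in both sets. This fallback, the comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined.

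Overlap meant at least 1 nt on the same strand. Gene overlaps were tested with Fisher's exact test, two-sided, against the 55521 annotated genes of the reference. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Tags per listed peak ran from 4 to 2151. Total reads per library are not in the tables, so library depth was not known. For 1 test, the depth of a knockdown library relative to its scramble library was read from the smallest steps between enrichment values, which assumes that they follow the scaling of the control library. It came to 68.6% and 85.7% for Mettl14 and to 68.7% and 74.7% for Mettl3. Listed gene IDs numbered 6097, of which 6026 (98.8%) were in the GENCODE mouse annotation, release M21. Of the 6026, 6022 overlapped their annotated position. Peak centres were assigned to coding sequence, UTRs or a stop codon window of 200 nt. GGACT and DRACH motifs, in which D is any base but C, R a purine and H any base but G, were counted per kb. They were compared with same-length stretches of the same transcripts in 10000 draws, for peaks on transcripts only. For the shared scramble library, 100 draws lost each scramble peak at random in 2 unchanged libraries, at the rate of absence from the other scramble library within 16 strata of enrichment and width.

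The 12 lists were m6A machinery, pluripotency, ectoderm and neural development, mesoderm and endoderm development, trophectoderm, developmental signalling, chromatin regulators, cell cycle, cytosolic ribosomal proteins, housekeeping and cytoskeleton, p53 and stress response, and markers of feeder fibroblasts. Each was tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the lists at 0.05. The rule for named genes took, for each knockdown, the 10 genes lower and the 5 genes higher in both sets with the largest mean log2 change. It also took Mettl3, Mettl14 and Wtap, and up to 4 members of each list with the largest changes. Because lost peaks carry no fold, 6 genes per knockdown with every scramble peak lost in both sets and the highest peak score were added after the tables were seen. Other genes named were chosen after their values were seen.

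Alternatives were an FDR under 1%, minimums of 2-fold and 4-fold, a minimum of 10 tags, overlap of 50% of the shorter peak, regions in place of genes, other backgrounds, the median fold set to 0, same-set pairs and each set left out. Alternatives chosen after seeing the data were unscaled folds, lost and new peaks alone, an equal score limit, genes listed in both tables compared, peaks found in both scramble libraries, and genes with a scramble peak in both sets. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

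Peak overlap, the gene call with Mettl14 peaks, gene overlap, gene lists, motif counts and transcript coordinates were tested on simulated data. The other steps were not. Removed peaks lying apart from every kept peak were called absent in 100% of cases, a result that the construction fixed, so it checks the code only. With a 2-fold minimum, genes lowered 4-fold were called in 100% of cases in both sets, and genes lowered exactly 2-fold in 56.5% and 51.5%. At most 0.139% of unchanged genes were called lower. This simulation held shared peaks alone, with less spread than the SD of 0.92 and 0.83 (log2) across real shared Mettl14 peaks. The main gene calls have no fold minimum, so it gives no error rate for them. Independent gene lists gave p under 0.05 in 6.5% of 200 draws. A planted list with 8 of 38 members called passed in 100% of 100 draws. Its overlap was the same in every draw, so this checks the code and does not measure power. A planted motif gave a ratio of 2.77, and sequence with none planted gave 0.986 (permutation p = 0.644).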

Results

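N6-methyladenosine (m6A), an internal mark of mRNA, was mapped by antibody pull-down of RNA fragments in J1 mouse embryonic stem cells. The question was how the map differed after knockdown of Mettl3, the catalytic subunit of the m6A writer complex, or of Mettl14, its RNA-binding partner. There were 3 groups with 2 IP libraries each, in 2 sets of 1 scramble, 1 Mettl14 knockdown and 1 Mettl3 knockdown library. The scramble libraries held 7886 peaks in set 1 and 5438 in set 2, covering 5212 and 4254 kb. The Mettl14 knockdown libraries held 5717 and 4367 peaks over 3386 and 3063 kb. The Mettl3 knockdown libraries held 5087 and 4577 peaks over 3225 and 3052 kb. Median tags per peak were 70 to 96 for the knockdown copies of shared peaks and 38 to 53 for lost peaks. Median scramble enrichment went the other way, at 14.1 to 15.6 for shared and 23.4 to 28.1 for lost peaks. Neither Mettl3 nor Mettl14 mRNA had a listed peak in any table, and the tables hold no expression values, so the knockdown itself was not checked here. Wtap, a further subunit of the writer complex, lost its coding-sequence peak (chr17, 12967381 to 12968223 in set 1) in all 4 tables. Its 3' UTR peak had log2 changes of 2.10 and 0.66 with Mettl14 knockdown and 1.17 and -0.61 with Mettl3 knockdown in the authors' deposited tables. The genome build was mm10. Values are given by set, and the spread between sets covers only these samples, which may be technical replicates.

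With Mettl14 knockdown, Shb, Itpkb, Egfr and Irs2 were among the genes with the largest decreases in both sets. Shb, an adaptor of receptor tyrosine kinases, had log2 changes of -3.45 in set 1 and -5.13 in set 2 in the authors' deposited tables, at neighbouring peaks, and the peak at the set 2 site had -1.28 in set 1. The coding-sequence peak of Itpkb, an inositol trisphosphate kinase (chr1, 180332953 to 180334211), had -2.75 and -2.80 in the authors' deposited tables. Egfr, the epidermal growth factor receptor, had a peak at its stop codon (chr11, 16911561 to 16912087) with -3.47 and -2.91 in the authors' deposited tables. Irs2, an insulin receptor substrate, had -3.02 at a 3' UTR peak in set 1, which had -1.05 in set 2, and -1.88 at a coding-sequence peak in set 2 in the authors' deposited tables. The other genes with the largest decreases were Tmem246, Sertad4, Pknox2, Col27a1, Prss23 and Psd3, whose values ran from -4.85 to -1.86 in the authors' deposited tables and came from different peaks in the sets for Psd3 and Tmem246. Every scramble peak was lost in both sets in Evi5l, Mmp28, Gna15, Mafa, Cep128 and Gm14221. The peaks of Cep128 and Gm14221 lay outside annotated exons of these genes. Mafa encodes a transcription factor of pancreatic beta cells and Mmp28 a secreted metalloproteinase. The largest increases were in Gpr157, an orphan receptor, with 1.62 and 1.89, and in Cmklr1, the chemerin receptor, with 1.69 and 1.78 at neighbouring peaks, in the authors' deposited tables. At the set 2 site of Cmklr1 the set 1 peak had 0.18 in the authors' deposited tables. These are enrichments over narrower calls with fewer tags, since the knockdown peaks of Gpr157 held 10 and 12 tags and its scramble peaks 29 and 31. Tmem132d, Tspyl1 and Rasal1 followed, with values from 0.35 to 2.21 in the authors' deposited tables.

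Of the set 1 scramble peaks, 3414 (43.3%, 95% Wilson interval 42.2 to 44.4) had no overlapping Mettl14 knockdown peak. In set 2 there were 2495 such peaks (45.9%, interval 44.6 to 47.2). New peaks numbered 1080 (18.9% of knockdown peaks, interval 17.9 to 19.9) and 1354 (31.0%, interval 29.7 to 32.4). Genes lower numbered 3145 in set 1 and 3099 in set 2, and 1657 were lower in both. Genes higher numbered 1492 and 869, and 302 were higher in both. Without the authors' scaling constants 1325 genes were lower and 521 higher in both sets, and with the median set to 0 there were 1266 and 625. Shared peaks numbered 4710 and 3060, with a median log2 change of -0.06 and -0.59 in the authors' deposited tables, and 54.6% and 84.8% of them were lower. Without the scaling constants the medians were 0.08 and -0.23 and the lower shares 45.1% and 65.7%. Each fold compares regions called separately, and the median width of a knockdown peak was 82.9% to 92.7% of that of its scramble peak, by direction and set. The sign of the set 1 median thus turned with the scaling. Between the scramble libraries themselves, 41.8% of set 1 peaks were absent from set 2 and 17.4% of set 2 peaks from set 1. Absence also depends on the length of the other list, which held 5438 scramble against 5717 Mettl14 knockdown peaks for set 1 and 7886 against 4367 for set 2, so no order is read from these shares.

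**Figure D1:**
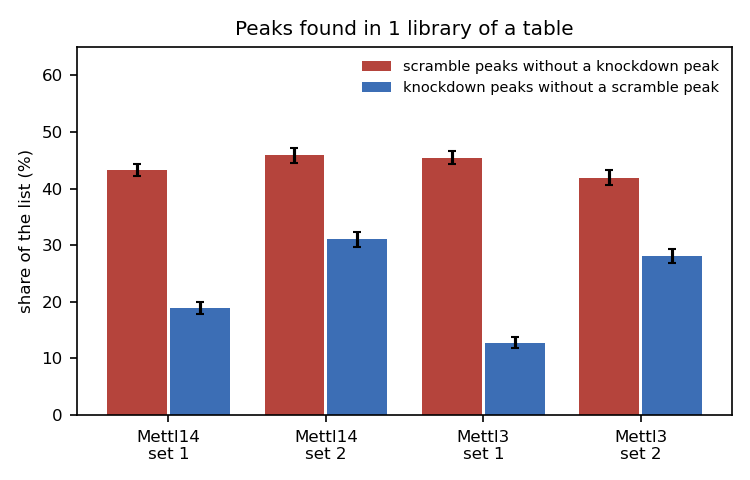
Lost peaks as a percent of the scramble list and new peaks as a percent of the knockdown list in each of the 4 tables, with Wilson intervals. The shares have different denominators. Counted as peaks, which the figure does not show, lost peaks outnumbered new peaks in every table, by a factor of 1.77 to 5.52.

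Peaks lost in one set tended to be lost in the other. Among 4591 set 1 scramble peaks found in both scramble libraries, 24.6% were lost with Mettl14 knockdown in set 1 and 37.2% in set 2. Both losses met in 877 peaks, where 421 would be due to chance (odds ratio 10.9, Fisher's exact test, two-sided, p = 2.51e-228). Within strata of enrichment and width the odds ratio was 8.17. Loss also went with absence from the other scramble library, which holds no knockdown, with odds ratios of 6.90 and 8.79 over all scramble peaks of set 1 and set 2. By genes, the odds ratio against all annotated genes was 39.3, with a p too small for the software to separate from 0. Most annotated genes have no peak to lose, and among genes listed in both tables the odds ratio was 1.98 (exact p = 1.92e-21). Opposite calls were made for 1038 genes, of which 747 were higher in set 1 and lower in set 2. Across 2197 genes with a shared peak in both sets, the log2 changes in the authors' deposited tables had a Pearson r of 0.247 and a Spearman rho of 0.265. The sign was the same in both sets for 57.5% of these genes. Genes are not independent replicates, so no p is given for these correlations. Peaks are not independent of each other either. The Fisher p-values of this and the later overlaps between tables count genes or peaks as independent, so they may be too small.

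In the Mettl3 knockdown, Shb and Itpkb again stood among the largest decreases, with -2.35 and -5.12 for Shb, at neighbouring peaks, and -3.09 and -2.49 for Itpkb in the authors' deposited tables. At the set 2 site of Shb the set 1 peak had -0.80 in the authors' deposited tables. Bcl2l11, which encodes the pro-apoptotic protein Bim, had a peak (chr2, 128134886 to 128135158, outside annotated exons of the transcript used) with -3.01 and -3.10 in the authors' deposited tables. Cdcp1, a transmembrane substrate of Src kinases, had a stop codon peak (chr9, 123173170 to 123173971) with -3.12 and -2.75 in the authors' deposited tables. Flnc, a muscle filamin, had -2.09 and -3.30 in the authors' deposited tables. Olfml2b, Synpo2l, Tmcc3, Fam84b and Prss23 completed the group, with values from -4.93 to -1.55 in the authors' deposited tables. For Fam84b in set 2 the knockdown call was much wider than the scramble call, so its -4.35 in the authors' deposited tables is not a fold over 1 region. Every scramble peak was lost in both sets in Rimbp3, Maml2, Acot7, Ablim1, Zfp783 and Lrrc75a. The peak of Acot7 lay outside annotated exons of the gene. Maml2 is a coactivator of Notch signalling and Ablim1 an actin-binding protein. The largest increases were in Thpo, which encodes thrombopoietin, with 4.29 and 1.02, and in Lrriq4, with 4.02 and 1.01, in the authors' deposited tables. Meis1, a homeobox factor of blood and limb development, followed with 2.44 and 2.33 in the authors' deposited tables, from knockdown peaks of 11 and 16 tags. Ccdc88b and Lrrn1 had values from 0.11 to 4.35 in the authors' deposited tables.

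Of the scramble peaks, 3584 (45.4%, Wilson interval 44.4 to 46.5) in set 1 and 2277 (41.9%, interval 40.6 to 43.2) in set 2 had no overlapping Mettl3 knockdown peak. New peaks numbered 649 (12.8%, interval 11.9 to 13.7) and 1284 (28.1%, interval 26.8 to 29.4). Genes lower numbered 2629 and 3274, and 1308 were lower in both sets. Genes higher numbered 1838 and 693, and 227 were higher in both. Without the scaling constants 1161 genes were lower and 612 higher in both sets, and with the median set to 0 there were 1216 and 579. The 4516 and 3337 shared peaks had a median log2 change of 0.22 and -0.91 in the authors' deposited tables, and 35.2% and 93.0% of them were lower. Without the constants the set 2 median was -0.20 and the lower share 63.0%, so set 1 and set 2 went opposite ways under both scalings. The scramble libraries' own absences of 41.8% and 17.4% again rest on lists of other lengths, 5438 and 7886 peaks against 5087 and 4577. In set 2, higher shared peaks had a median width of 64.3% of their scramble peaks and lower ones 87.8%.

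Among the 4591 peaks found in both scramble libraries, 26.0% were lost with Mettl3 knockdown in set 1 and 31.8% in set 2. Both losses met in 842 peaks against 379 by chance (odds ratio 10.8, Fisher's exact test, two-sided, p = 1.43e-235), and the odds ratio within strata was 7.56. Loss went with absence from the other scramble library with odds ratios of 7.55 and 14.0 over all scramble peaks of set 1 and set 2, so an overlap of this size also occurred with a scramble library in place of the second knockdown library. By genes the odds ratio was 25.6 against annotated genes and 1.33 among genes listed in both tables (exact p = 0.000422). Against genes listed in any table it was 0.756 (exact p = 7.91e-08), below 1, so the gene-level overlap rests on the background. Opposite calls were made for 1386 genes, of which 1166 were higher in set 1 and lower in set 2. Across 2353 genes, r of the log2 changes in the authors' deposited tables was 0.201 and rho 0.207. Only 37.0% of these genes had the same sign in both sets.

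**Figure D2:**
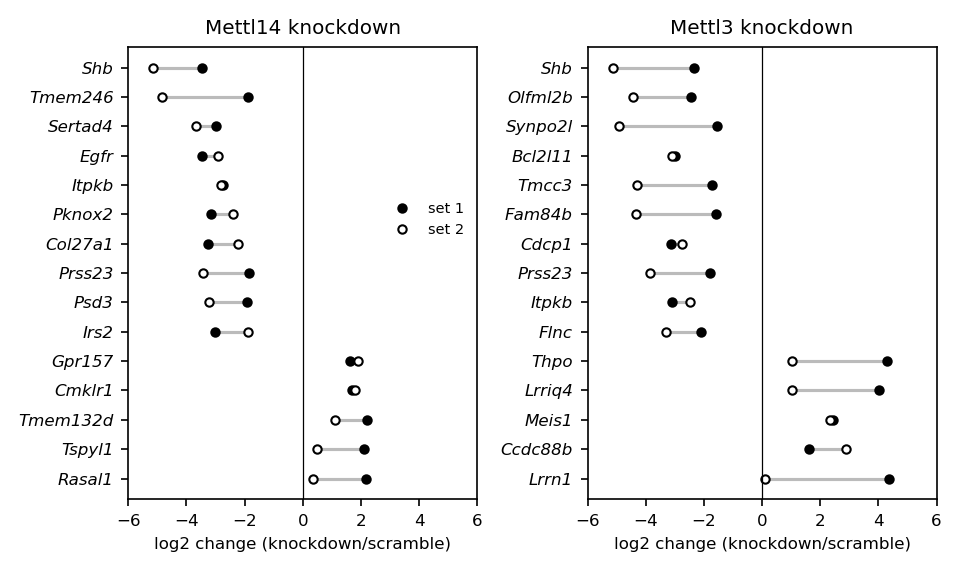
Log2 change of knockdown over scramble in the authors' deposited tables for the genes with the largest changes in each knockdown, with 1 point per set. For Itpkb the points lie at -2.75 and -2.80 with Mettl14 knockdown and at -3.09 and -2.49 with Mettl3 knockdown.

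The next comparison asked whether both knockdowns hit the same transcripts. Genes lower in both sets of both knockdowns numbered 917, among them Shb, Itpkb and Prss23, and 84 genes were higher in both sets of both. By peaks, 2720 of the 7886 set 1 scramble peaks were lost in both knockdowns, where independent lists would share 1552 (odds ratio 16.4), and 1802 of 5438 in set 2 against 1045 (odds ratio 13.5). The knockdowns of a set share its scramble library. Simulated against it, 2 unchanged libraries gave mean odds ratios of 2.47 and 2.66 (highest 2.87 and 3.34). The draws lost peaks independently within strata, with 294 joint losses on average in set 2, so they may understate the shared part. With the other scramble library in place of 1 knockdown library, odds ratios were 6.90 and 7.55 in set 1 and 8.79 and 14.0 in set 2. Part of the excess may thus come from the shared library, so it is not read as a common effect. Gsc, a homeobox factor of the organizer, Sox7, an endoderm factor, and Lrp5, a Wnt co-receptor, lost every scramble peak in both knockdowns and both sets, as did 259 genes in all. The peak of Gsc lay at its stop codon (chr12, 104471427 to 104471757). Fgf5, a growth factor of the primed epiblast, had a new peak at its stop codon in all 4 tables (chr5, 98275213 to 98275883 for Mettl14 knockdown in set 1). Zfp281, a zinc finger factor of pluripotent cells, had new coding-sequence peaks in all 4 tables (chr1, 136625225 to 136626788 for the first). Foxc1, a forkhead factor of mesoderm, had new peaks in all 4 tables as well.

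Pairs of tables with no shared library are free of a common scramble library. For Mettl14 in set 1 and Mettl3 in set 2, 805 of the 4591 peaks were lost in both against 360 by chance (odds ratio 10.6, Fisher's exact test, two-sided, p = 6.69e-225, and 7.40 within strata). For Mettl3 in set 1 and Mettl14 in set 2 there were 864 against 443 (odds ratio 7.99, exact p = 2.30e-186, and 5.86 within strata). By genes the odds ratios were 38.5 and 25.7 against annotated genes and 1.67 and 1.37 among genes listed in both tables. Against genes listed in any table they were 1.05 (exact p = 0.355) and 0.822 (exact p = 0.000159). Of the 4591 peaks, 517 (11.3%) were lost in all 4 tables, and 2254 (49.1%) were kept in all 4. The peaks lost in all 4 were narrower, with a median width of 457 against 862 nt. Their median enrichment in the set 1 scramble library was higher, at 19.7 against 14.4. The scramble libraries shared 57.5% of their covered length, scramble and knockdown libraries 43.7% to 52.0%, and knockdown libraries 52.5% to 62.4%. This share is capped where 1 library covers more than the other. Scramble libraries covered 5212 and 4254 kb and knockdown libraries 3052 to 3386 kb, so the order of pairs may follow in part from covered length. With 15 splits of the 6 libraries, the smallest exact permutation p that this design can give is 0.0667, which is the value found.

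**Figure D3:**
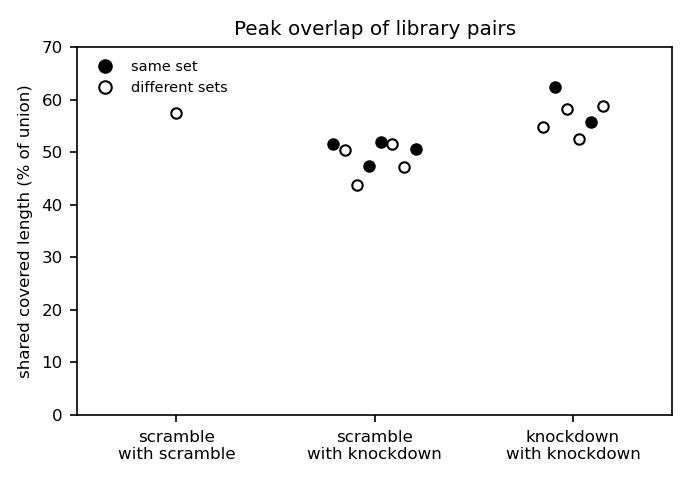
Shared covered length (percent) of each pair of the 6 IP libraries, by kind of pair. The scramble pair lies at 57.5%, above the 8 scramble and knockdown pairs at 43.7% to 52.0%. Unequal covered length of the libraries caps this share and was not held constant.

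Of the fixed gene groups, developmental signalling held the most genes lower in both sets. Its member Spry4 was higher in both sets with Mettl14 knockdown, at 0.24 and 0.02 in the authors' deposited tables. In set 1 with Mettl3 knockdown 8 members were lower and 9 higher, while lower members outnumbered higher ones in the other tables. Nodal, a morphogen of the gastrula, had a coding-sequence peak with log2 changes of -0.18 and -1.36 and a stop codon peak with -0.44 and -0.54 with Mettl14 knockdown in the authors' deposited tables. Gli3, a Hedgehog effector, had -1.08 and -0.70 with Mettl14 knockdown and -0.22 and -1.38 with Mettl3 knockdown in the authors' deposited tables. Smad1, a BMP effector, had a stop codon peak with -1.60 in set 1 that was lost in set 2 with Mettl3 knockdown in the authors' deposited tables. Dusp6, a phosphatase of ERK, had -1.18 and -1.45 with Mettl3 knockdown in the authors' deposited tables. Fgfr1, an FGF receptor, had -0.50 and -0.87 at different peaks with Mettl3 knockdown in the authors' deposited tables, and its set 2 value became 0.04 with the median set to 0. Of 38 members, 20 had a scramble peak in both sets against 2.36 by chance among all annotated genes (adjusted exact p = 9.73e-14). Without expression values, no background of expressed genes could be run for peak carriage in any list. With Mettl14 knockdown 8 members were lower in both sets and with Mettl3 knockdown 6, against all annotated genes (adjusted exact p = 0.000163 and 0.00294). Among the 3455 genes with a scramble peak in both sets, the 8 and 6 compare with 9.59 and 7.57 by chance (adjusted exact p = 1 for both).

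Of the pluripotency genes, 4 were higher in both sets with Mettl14 knockdown and 3 with Mettl3 knockdown. None of the 33 members was lower in both sets in either knockdown. A scramble peak in both sets was found for 11, against 2.05 by chance among all annotated genes (adjusted exact p = 6.88e-06). Klf4, a reprogramming factor, had a coding-sequence peak (chr4, 55530050 to 55531031) with 1.11 and 0.70 under Mettl14 knockdown and 1.37 and 0.73 under Mettl3 knockdown in the authors' deposited tables. Lifr, the LIF receptor, had 0.22 and 0.34, and Myc 0.23 and 0.22, with Mettl14 knockdown in the authors' deposited tables. Socs3, an inhibitor of LIF signalling, had 1.17 and 0.31 with Mettl3 knockdown in the authors' deposited tables. The 4 and 3 higher members gave adjusted exact p = 0.000372 and 0.00403 against annotated genes. Set by set the group was mixed, with 7 members lower and 6 higher in set 2 with Mettl3 knockdown. Against genes with a scramble peak in both sets, 3 of 11 were higher with Mettl14 knockdown (0.315 by chance, adjusted exact p = 0.0382) and 2 with Mettl3 knockdown (adjusted exact p = 0.0888). In that background, chosen after seeing the data, the absence of lower members gave adjusted exact p = 0.0063 for Mettl14 and 0.0544 for Mettl3. Against genes listed in any table no pluripotency call passed, with adjusted exact p = 0.0626 and 0.2 for higher members and 0.0967 and 0.316 for the absence of lower members.

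Chromatin regulators also carried many peaks, with 20 of 42 members against 2.61 by chance among all annotated genes, expressed or not (adjusted exact p = 5.84e-13). Tet2, a 5-methylcytosine dioxygenase, had 1.42 and 0.67 with Mettl14 knockdown in the authors' deposited tables. Kat6b, a histone acetyltransferase, had 0.74 and 0.19 with Mettl14 knockdown and 0.57 and 0.13, from different peaks, with Mettl3 knockdown in the authors' deposited tables. With Mettl14 knockdown 4 members were higher in both sets and with Mettl3 knockdown 2 (adjusted exact p = 0.00049 and 0.0386 against annotated genes). In the background of genes with a scramble peak in both sets, these became adjusted exact p = 0.664 and 0.653. In each knockdown 1 member was lower in both sets, against 9.59 and 7.57 by chance in that background (adjusted exact p = 0.000583 and 0.021). Against genes listed in any table these were 0.0113 and 0.0946 (exact). A gene with several peaks met the rule only if all of them went 1 way.

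Of 22 members of the m6A machinery, 10 had a scramble peak in both sets, and 4 were lower in both sets in each knockdown (adjusted exact p = 0.015 and 0.00959 against annotated genes). Cbll1, a subunit of the writer complex, Fto and Alkbh5, the m6A demethylases, were lower in all 4 tables, but without the scaling constants Cbll1 and Fto with Mettl14 knockdown and Alkbh5 with Mettl3 knockdown were higher in set 2. Of 25 ectoderm genes, 3 were lower in both sets with Mettl14 knockdown and 4 with Mettl3 knockdown (adjusted exact p = 0.0898 and 0.0105). They included Nes, an intermediate filament of neural progenitors, with -1.12 and -1.90, and Zic2, with -1.35 and -1.64, under Mettl14 knockdown in the authors' deposited tables. Pou3f1, a neural POU factor, had -0.99 and -1.75 with Mettl14 knockdown and was lower in both sets with Mettl3 knockdown, reaching -2.21 in set 2, in the authors' deposited tables. Of 34 mesoderm and endoderm genes, 4 and 3 were lower in both sets (adjusted exact p = 0.054 and 0.0779), and with Mettl3 knockdown 2, Foxc1 and Meis1, were higher (adjusted exact p = 0.0343).

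Of 18 p53 and stress genes, 4 and 3 were lower in both sets (adjusted exact p = 0.0104 and 0.0245), and with Mettl3 knockdown 2 were higher (adjusted exact p = 0.0146). Jun, an AP-1 factor, had a 5' UTR peak with -0.63 and -0.87 with Mettl14 knockdown in the authors' deposited tables, and Gadd45b lost every scramble peak in both knockdowns. Hspa1a and Hspa1b, both lower, are near-identical heat shock genes whose reads are hard to separate. Of 26 cell cycle genes, 2 and 3 were lower in both sets (adjusted exact p = 0.363 and 0.0544). Of 13 trophectoderm genes, 1 and 2 were lower (adjusted exact p = 0.558 and 0.0728). None of 34 cytosolic ribosomal protein genes and none of 16 housekeeping genes had a scramble peak in either set. For a peak in both sets, 2.12 and 0.996 would be due to chance (adjusted exact p = 0.325 and 0.677). Of 23 markers of feeder fibroblasts, 1 had a scramble peak in both sets against 1.43 by chance (adjusted exact p = 1). It was Ccn1, a secreted matrix protein, which was lower in both sets of each knockdown. For the machinery, ectoderm, mesoderm and p53 groups, no enrichment of lower members held among genes with a scramble peak in both sets (adjusted exact p from 0.974 to 1). The higher mesoderm and p53 members with Mettl3 knockdown did not pass there either (adjusted exact p = 0.417 for both), nor against genes listed in any table (0.471 and 0.365, exact).

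The last comparison asked where the peaks lie and whether they carry the m6A motif. Scramble peaks lay in coding sequence for 37.4% in set 1 and 42.1% in set 2, within 200 nt of a stop codon for 22.4% and 20.01%, and in the 3' UTR for 13.6% and 12.1%. Kept peaks lay in coding sequence more often (45.2% to 53.8% over the 4 tables) than lost peaks (26.9% to 30.5%) or new peaks (31.1% to 36.4%). No gene lay at 7.59% to 8.99% of kept peaks, but at 24.0% to 26.2% of lost and 24.0% to 29.8% of new peaks. Stop codon peaks made up 18.9% to 23.9% of kept and 18.3% to 21.3% of lost peaks, and 14.0% to 16.6% of new peaks. New peaks lay in the 5' UTR more often, at 5.7% to 9.6%. The GGACT motif occurred 1.71 and 1.64 times per kb of scramble peak in set 1 and set 2, or 1.37 and 1.31 times as often as in stretches of the same transcripts. Its permutation p was 0.0001 in each set, the smallest that the draws can give. For lost peaks the ratio was 1.31 to 1.43, for kept peaks 1.30 to 1.35 and for new peaks 1.40 to 1.58. In the central 100 nt, which sets aside the narrower width of lost peaks, the GGACT ratio was lower for lost than for kept peaks in each table, at 1.46 to 1.77 against 1.67 to 1.82. The DRACH ratio there was higher for lost peaks in 3 of 4 tables, at 1.16 to 1.23 against 1.16 to 1.22, and neither difference was tested. The broader DRACH motif occurred 22.3 and 21.6 times per kb of scramble peak in set 1 and set 2, against 20.3 and 20.1 in stretches of the same transcripts (permutation p = 0.0001 each). Over whole peaks, DRACH sites were denser in lost than in kept peaks by 1.14 per kb for Mettl14 in set 1 and by 1.28 and 1.04 for Mettl3 (permutation p = 0.0001 each). For Mettl14 in set 2 the difference was -0.527 (permutation p = 0.0129). GGACT was denser in lost peaks by 0.0931 per kb for Mettl14 in set 1 (permutation p = 0.0345), with p from 0.283 to 0.955 in the other tables. The motifs thus gave no single order of lost and kept peaks.

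**Figure D4:**
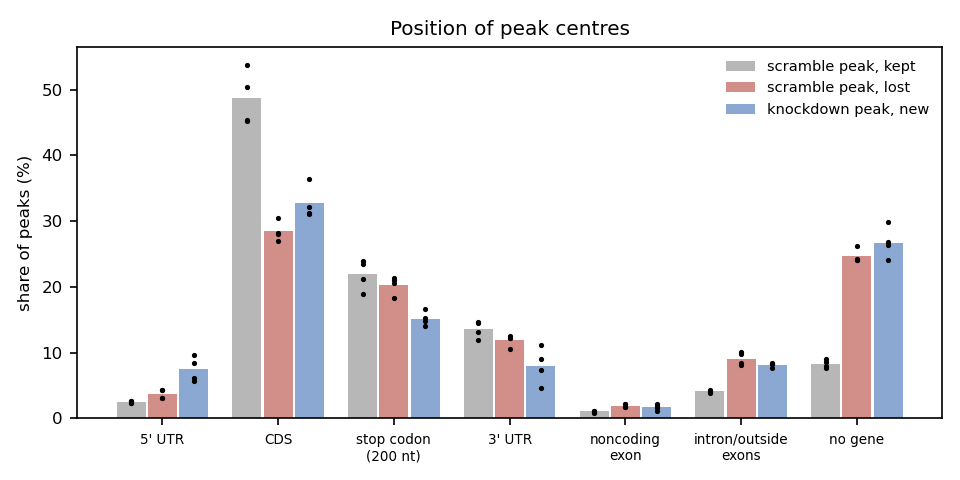
Share of kept, lost and new peaks (percent) by position in the transcript, for each of the 4 tables. Kept peaks lay in coding sequence in 45.2% to 53.8% of cases and lost peaks in 26.9% to 30.5%.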

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

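Tests chosen after the results were seen were unscaled folds, lost and new peaks alone, the equal score limit, genes listed in both tables compared, peaks found in both scramble libraries and the background of genes with a scramble peak in both sets. In every setting run, genes lower in both sets outnumbered genes higher. The scramble list was the longer one in every table, with 7886 peaks against 5717 and 5087 in set 1 and 5438 against 4367 and 4577 in set 2. Listed lost peaks counted as lower in each setting, so this direction may follow from list length and is no check independent of it. The equal score limit could only drop new peaks or turn shared peaks into lost ones. The fold minimums applied to shared peaks only. Lost and new peaks carry no fold and were called at every minimum, so these counts are not numbers of genes changed 2-fold or 4-fold. Genes lower in both sets with Mettl14 knockdown (1657) numbered 472 at an FDR under 1%, 933 at 2-fold, 780 at 4-fold and 754 by lost and new peaks alone. With Mettl3 knockdown (1308) they numbered 441, 931, 725 and 690. Genes higher numbered 117, 164, 167 and 175 with Mettl14 knockdown (302) and 107, 121, 91 and 88 with Mettl3 knockdown (227) in the same order. With the median fold set to 0 they were 625 and 579, with unscaled folds 521 and 612, and with an equal score limit 173 and 77. Counted as regions, 2910 and 644 were lower and higher with Mettl14 knockdown, and 2344 and 494 with Mettl3 knockdown. From 1 set alone, the genes lower ranged from 3099 to 3145 and higher from 869 to 1492 for Mettl14, and from 2629 to 3274 and 693 to 1838 for Mettl3.

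At an FDR under 1%, the overlap of lower regions between tables fell from 48.9%, 45.5%, 50.2% and 44.2% to 27.5%, 36.0%, 43.1% and 24.6%. Against genes listed in any table, the gene overlap odds ratio was 0.756 for Mettl3 and 1.05 and 0.822 between knockdowns, because genes missing from a table count against overlap. Lists enriched for lower members numbered 3 for Mettl14. They were 7 for a call in either table, 0 against genes listed in any table, 0 against genes with a scramble peak in both sets, and 5 to 6 from 1 set alone. For Mettl3 the 4 lists became 8, 0 and 0 under those settings, 0 at an FDR under 1% and 1 by lost and new peaks alone. Below chance, with adjusted exact p = 1, were the machinery with Mettl14 knockdown at an FDR under 1% and, against genes with a scramble peak in both sets, the machinery with Mettl14 knockdown and signalling and p53 genes in both knockdowns. At an FDR under 1% the DRACH ratio of lost peaks with Mettl14 knockdown in set 2 was 1.03 (permutation p = 0.0949). Stop codon shares of lost peaks were then 23.3%, 18.5%, 23.1% and 22.1%.

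Some set 2 directions turned without the scaling constants and with the median set to 0. For Mettl14 these were Cbll1 (0.15 and 0.38), Fto (0.18 and 0.41), Fzd7 (0.17 and 0.40) and Kdm6b (0.16 and 0.39). For Mettl3 these were Ythdf3 (0.059 and 0.26), Alkbh5 (0.16 and 0.35), Wee1 (0.056 and 0.25) and, with the median set to 0, Fgfr1 (0.040). Unless stated, the cause was not tested. No paired analysis was possible by replicate number because the columns carry no replicate numbers of the labels. Each fold already compares a knockdown library with the scramble library of its own set. A test of the shared peaks' log2 changes over the 2 sets was left out. Not run were edgeR, DESeq2 and pseudocount alternatives, since the tables give no value per library over common regions. In a central window of 100 nt the GGACT ratio of lost peaks was 1.46 to 1.77, below that of kept peaks (1.67 to 1.82) in every table, while DRACH was above it in 3 of 4. This window does not apply to positions read from peak centres. Unknown read totals limit every statement on absent peaks.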

Other observations

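All tests in this part were chosen after the results were seen. Some genes went opposite ways in the knockdowns. Gpr157 was higher in both Mettl14 sets and lost its peak in both Mettl3 sets, while Meis1 and Ccdc88b were lower in both Mettl14 sets and higher in both Mettl3 sets. Meis1 had only -0.29 with Mettl14 knockdown in set 1 in the authors' deposited tables. The Mettl3 calls of Ccdc88b were narrow parts of wide scramble peaks (6853637 to 6853830 within 6853043 to 6853838 in set 1), so its increases are not folds over 1 region. Foxe1, a forkhead factor of the thyroid, and Arid5b, a chromatin cofactor, were among 16 genes higher with Mettl14 and lower with Mettl3 knockdown in both sets. Eya1, an otic and kidney factor, was among 14 genes with the reverse pattern, out of 3672 genes listed in all tables. Independent calls would give 67.7 and 65.4 such genes, but the knockdowns share a scramble library within each set, whose part in the shortfall was not simulated for genes. By peaks, unchanged libraries simulated against that library gave odds ratios of 2.47 and 2.66 for loss in both, where 16.4 and 13.5 were found. The draws lost peaks independently within strata and may understate the shared part, so they do not settle it. With the other scramble library in place of 1 knockdown library, odds ratios were 6.90 and 7.55 in set 1 and 8.79 and 14.0 in set 2.

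Counted by peaks in place of genes, chromatin regulators kept more of their scramble peaks than other genes with Mettl3 knockdown. With Mettl3 knockdown, 22.4% and 10.5% of chromatin peaks were lost in set 1 and set 2, against 41.1% and 36.8% in other genes (adjusted exact p = 0.0266 and 0.00626). With Mettl14 knockdown, 25.9% and 18.4% were lost, which did not pass the correction (adjusted exact p = 0.17 and 0.0518). Of pluripotency peaks, 1 of 15 and 1 of 12 were lost with Mettl14 knockdown (adjusted exact p = 0.0666 and 0.117), and 2 of 15 and 0 of 12 with Mettl3 knockdown (adjusted exact p = 0.137 and 0.0325), so 1 of 4 tables passed. Signalling peaks were lost in 16.2% and 16.1% with Mettl3 knockdown (adjusted exact p = 0.0252 and 0.0921) and in 18.9% and 28.1% with Mettl14 knockdown (adjusted exact p = 0.0666 and 0.408). These tests count peaks as independent, but the 58 and 38 chromatin peaks of set 1 and set 2 lay in 27 and 21 genes. Their p-values may thus be too small. Peak width differed between lost and kept peaks and was not held constant here.

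The loss of scramble peaks was weighed against depth and against differences between libraries. With scores scaled by the relative depth read from the tables, 84.4% of the lost peaks would still reach the list limit for Mettl14 in set 1 and 45.3% for Mettl3 in set 1. Relative depth was near equal there (68.6% and 68.7%) and the list limits differed, and in set 2 the limits alone let 100% pass, so lower depth stays open in every table. Pairs within the scramble or the knockdown group shared 7.86 points more covered length than pairs across them, and the highest other split gave 2.82, but 15 splits are too few for a share under 0.05. Scramble libraries also covered more than knockdown libraries, which caps the share of pairs across them and was not held constant. Variation between libraries and an effect of the knockdowns on m6A both stay open.

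The median change of shared peaks differed between the sets. With the authors' scaling constants the set medians were -0.06 and -0.59 for Mettl14 and 0.22 and -0.91 for Mettl3 on the log2 scale, so the constants widened the difference. Without them the medians still differed, by 0.31 for Mettl14 and 0.42 for Mettl3. The bootstrap intervals did not overlap, which argues against the constants as the whole cause. These intervals were drawn over the peaks of 1 library pair per set, so they do not cover the spread between library preparations. No biological explanation was tested, since the design gives none for a difference between sets. A difference between library preparations was not tested and stays open.

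New peaks in the knockdowns were weighed against calls on background and against the list limits. Of the new peaks for Mettl14 in set 1 and Mettl3 in set 1 and set 2, 664 of 1080, 439 of 649 and 828 of 1284 lay on transcripts. Their GGACT density was at least 1.44 times that of stretches of the same transcripts, at the listed FDR and under 1%. This argues against calls without the m6A motif as the whole cause on transcripts. Peaks in no gene (24.0% to 29.8%) and in introns or outside exons (7.70% to 8.41%) were not tested and stay open. For the 881 of 1354 in Mettl14 set 2 the ratio was 1.40 at the listed FDR and 1.06 under 1% (permutation p = 0.541), so such calls stay open there. In set 2, at least 70.1% of new peaks scored below the lowest scramble score, so a lower list limit is a candidate explanation there. For Mettl14 in set 1 the share was 49.3%, which leaves this open, and for Mettl3 in set 1 it was 0%, as the knockdown limit was not lower there. Changed RNA levels were not tested.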
